A study of Mus musculus with 6 samples.

How the data were processed

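RNA from the eWAT of 3 db/db and 3 db/+ mice, aged 10 weeks, was profiled on 6 two-colour Agilent arrays. Per the labels' protocols, total RNA was amplified in 2 rounds and labelled, with the individual mouse in Cy5 and a lean control in Cy3 on all arrays and no dye swap. Per the file headers, all 6 mice and the pool of lean eWAT in the Cy3 channel were vehicle-treated; the vehicle and the mice in the pool are not given in the sources used here. Per the submitters' processing notes, arrays were read with Agilent Feature Extraction 8.5.1.1.

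The authors deposited a table of 23556 probes with, per array, an intensity of each channel and a p-value. The deposited intensities are on an arbitrary normalized scale, and 97.3% of them are whole multiples of 0.01 (to within 1e-06 of a step), so ratios of dim probes move in coarse steps and between 24.6% and 39.6% of the ratios of an array are exactly 0. The error model behind the deposited p-value, the background correction and the normalization are not given in the sources used here, and neither is the reason why between 50 and 201 probes per array have no value. The authors also deposited a series matrix of 23555 probes, whose log10 values equalled log10 of the mouse over the pool intensity of the table to within 0.005 on every array; the median log2 ratio of each array was 0.0. The 3 db/db columns of the table carry mouse numbers rather than replicate numbers and were used as db/db arrays without a replicate number; values for a numbered replicate come from the series matrix.

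Bright probes crowd at a ceiling: between 1 and 80 probes per array lay within 1% of its highest Cy5 intensity. Of the genes tested, 108 did so in either channel on at least 1 array, 23 of them called, and the sizes of their changes are approximate.

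Ratios were taken as log2 of the Cy5 over the Cy3 intensity, without further normalization or filter on dim probes. Gene symbols were updated through a RefSeq gene table: 17207 probes had a current symbol, 318 were renamed by accession, 1790 by synonym, 7 named by accession alone, and 2017 kept the name in the file, which left 2217 probes without a name and gave 17086 genes. A gene was represented by its probe with the highest mean intensity among those measured on all 6 arrays, or else among those with at least 2 values per group. Preferring fully measured probes was decided after missing values were seen. Among the 249 called genes with several probes, 77 had another probe of opposite sign.

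The comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, db/db minus db/+, no block), with Benjamini-Hochberg adjustment over 17024 genes and a threshold of 0.05. Fold changes are given on the log2 scale with the moderated standard error. The prior had 0.81 degrees of freedom beside 4 residual ones. The mean ratio of the 3 db/+ arrays was tested against 0 in the same fit. Lists of 22 pathways and 12 cell types, with 693 places of which 616 matched a named probe, were tested on the members with enough values with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over all 34 lists. The lists, the tests, most alternatives and the naming rule were fixed before the data were examined. The rule named Lepr, 10 preset genes, the 5 largest rises and 5 largest falls among calls measured on all 6 arrays whose groups did not overlap, and the 3 largest changes of each list with at least 3 calls. Not every gene selected by the rule is given in the text, while counts over named genes cover all of them. Cst8, Lcn10, Cd163, Mrc1, Folr2, Lyve1, Clec10a, Cpt1b, Ucp1, Egfl7, Asns, Ctss, Ifng, Krt18, Msln, the intense epididymis markers, Dcstamp, Gas6, Ocstamp, Retnla, Cd209f and Cd209b fall outside it and were chosen after their values were seen. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

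The fit was tested on simulated data with the intensities and spread of the 17024 genes, rounding included and 200 genes changed. The changed genes were drawn from those outside the dimmest 25%, so the shares recovered do not cover the dimmest genes. The fit recovered 20% of genes changed 1.5-fold, 38% of those changed 2-fold, 84% of those changed 4-fold and 92% of those changed 8-fold. It made 69 false calls among unchanged genes, of which 62 had no spread in either group. With no gene changed, 5 simulations gave between 39 and 60 calls after rounding, of which between 38 and 58 had no spread in either group, and 0 calls without rounding. In these simulations the calls made with no gene changed thus came from the rounding of intensities. Each gene varied independently, with 1 spread for both groups and 1 Cy3 intensity for all arrays. The simulations therefore cannot show false calls from variation that genes share on an array. In the real data 20 calls had no spread in either group.

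Alternatives covered the scaling of ratios, loess within arrays, the series matrix, the Cy5 channel alone, dim genes, the choice of probe, the variance model, the replicate number as a block, the omission of each array, db/db against the pool alone, other thresholds and other list tests. Those added after the data were seen were db/db replicate 1 alone, the epididymis marker median as a covariate, noise in place of rounding, the omission of genes without spread and a minimum mean intensity of 0.1.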

Results

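The series profiled epididymal white adipose tissue (eWAT), the fat pad beside the epididymis, from obese db/db mice and lean db/+ controls at 10 weeks of age. db/db mice lack a working long form of the leptin receptor, and the labels describe them as obese and severely hyperglycemic. Each of 6 two-colour arrays held the RNA of 1 mouse in Cy5 and a pool of lean control eWAT in Cy3, with 3 arrays per genotype, and the labels call the samples biological replicates. The deposited table gave between 23355 and 23506 measured probes per array. Signals were low for many probes: between 31.7% and 37.9% of the Cy5 intensities of an array were at or below 0.05 on the authors' scale, whose highest values lay between 26.8 and 30.5. The number of arrays limits the precision of every value. The question stated for the series was which genes are higher or lower in db/db than in db/+ eWAT.

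Lepr, the gene that carries the db mutation, had a log2 fold change of -0.12 ± 0.31 (SE, n = 3 per group; limma adjusted p = 0.864) and was dim, with a mean Cy5 intensity of 0.0867 in db/+ and 0.0767 in db/db. The position of its probes relative to the mutation is not given in the sources used here, so this value checks nothing about the labels. Lep, which encodes leptin, was higher in db/db by 1.45 ± 0.21 on the log2 scale (SE, adjusted p = 0.0329). Its log2 ratios were 1.69, 1.47 and 1.16 in the 3 db/db mice against 0.29, 0.00 and -0.32 in the 3 db/+ mice. Resistin (Retn) fell by 2.61 ± 0.38 (adjusted p = 0.0317). Pparg, the nuclear receptor that drives adipocyte differentiation, fell by 1.20 ± 0.20 (adjusted p = 0.0419). Slc2a4, the insulin-responsive glucose transporter GLUT4, fell by 1.33 ± 0.23 (adjusted p = 0.0419). Adiponectin (Adipoq) had a log2 fold change of -2.08 ± 0.42 and missed the threshold (adjusted p = 0.0564); its brighter probes had no value on 3 and 2 of the arrays, and the probe used was measured on all 6. Tnf had a log2 fold change of -0.05 (adjusted p = 0.664) on its brightest probe, while another, dimmer probe of the gene gave 0.75.

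Across the genome, 1150 of 17024 genes differed between db/db and db/+ eWAT at an adjusted p under 0.05, of which 502 were higher and 648 lower in db/db (43.7% higher). Of these, 356 differed at least 2-fold, 166 of them higher and 190 lower. Among calls measured on all 6 arrays whose groups did not overlap, the largest rises were in Il1rn, the interleukin-1 receptor antagonist (4.37 ± 0.36 on the log2 scale, SE), Olr1, a scavenger receptor for oxidised lipoprotein (4.32 ± 0.26), Ppp1r3a, a glycogen-targeting subunit of protein phosphatase 1 (3.79 ± 0.19), Egr2 (3.68 ± 0.64) and Atp6v0d2, a subunit of the vacuolar proton pump (3.51 ± 0.26). By the same limits the largest falls were in Cyp2e1, a cytochrome P450 (-4.33 ± 0.13), Cfd, which encodes adipsin (-4.13 ± 0.28), Mogat1, a monoacylglycerol acyltransferase (-4.04 ± 0.37), Sult1e1, the estrogen sulfotransferase (-3.60 ± 0.37), and Angpt1, a ligand of the endothelial receptor Tek (-2.84 ± 0.17). The sizes for Mogat1, Ppp1r3a and Olr1, and with them their places in this order, are approximate. Their mean Cy5 intensity was 0.0367 for Mogat1 in db/db and 0.0400 for Ppp1r3a and 0.0567 for Olr1 in db/+, a few steps of 0.01. In 26.1% of the genes measured on every array the 3 db/db ratios did not overlap the 3 db/+ ratios. Chance gives 10% on average for genes without tied ratios, and less with ties. Genes vary together on an array, so the share of a single split can lie far from that average.

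The count of 1150 depended strongly on single arrays and on the scaling: it was 167, 116 and 54 without db/+ replicates 1, 2 and 3 and 3417, 249 and 580 without db/db replicates 1, 2 and 3. It was 0 by limma after quantile normalization of the ratios (2176 at an unadjusted p under 0.05), 570 from the Cy5 channel alone and 6672 with array weights. Quantile normalization gives every array the same spread of ratios. Before it, the SD of the log2 ratios was 0.23 to 0.28 on db/+ arrays and 0.53 to 0.68 on db/db arrays. The array weights gave 1 db/db array 5.45 and the other db/db arrays 0.406 and 0.164, so that count leans on 1 db/db mouse. Of 60 genes past the threshold that the naming rule selected, 12, 12 and 5 stayed past it without db/+ replicates 1, 2 and 3, and 58, 18 and 28 without db/db replicates 1, 2 and 3. The balance of directions also moved: the share of higher genes was 57.4% without db/+ replicate 3, 58.6% without db/db replicate 2, 60.3% with the epididymis marker median as a covariate and 63.3% for db/db replicate 1 alone. Among the calls, 62 lay in the dimmest 25% of genes, and 20 had no spread within either group, a consequence of intensities deposited in steps of 0.01.

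**Figure D1:**
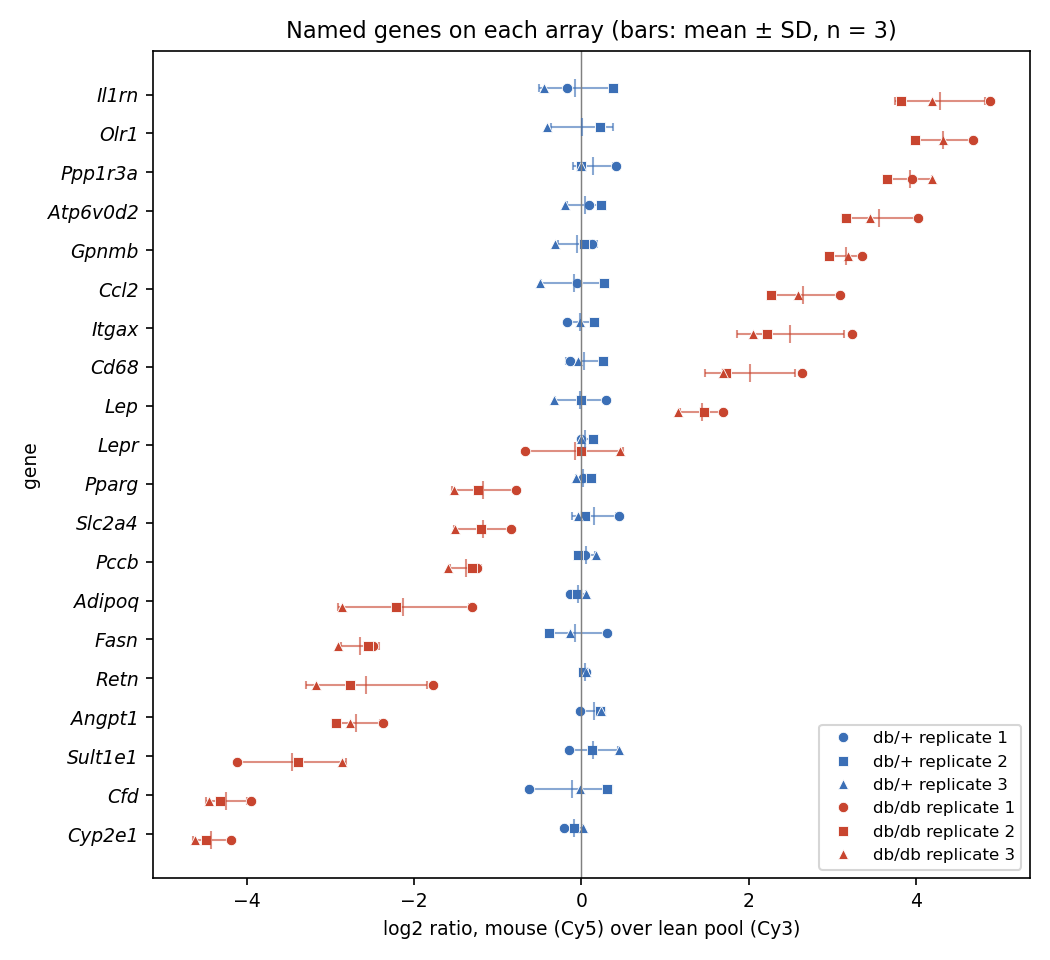
Log2 ratio of each mouse (Cy5) over the lean pool (Cy3) for 20 named genes, with db/+ mice in blue, db/db mice in red and a marker shape per replicate; horizontal bars give the mean ± SD (n = 3 per group). Lep lies between 1.16 and 1.69 in the db/db mice, Cyp2e1 between -4.62 and -4.19, and the Lepr ratios of both genotypes overlap.

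Markers of epididymis epithelium, included because the fat pad is dissected from that organ, separated the arrays within the db/db group. The median log2 ratio of the 12 measured markers was 3.87 and 4.22 in db/db replicates 2 and 3 and -1.68 in db/db replicate 1, against 0.67, 0.05 and -1.81 in the 3 db/+ mice. Adam7 and Gpx5 both had a mean Cy5 intensity of 18.8 in db/db, against 0.517 and 3.42 in db/+, and Cst11 had 12.4 in db/db and 0.163 in db/+. Adam7 and Gpx5 were within 1% of the highest Cy5 intensity on 1 db/db array, which makes their ratios there approximate. The list was higher in db/db by camera (median log2 fold change 2.53, adjusted p = 0.02; adjusted p = 0.68 with an estimated correlation), although only 1 of its 12 members, Cst8, passed the gene-level test, with values on 4 arrays. The list did not pass without db/+ replicate 3 (adjusted p = 0.079), db/db replicate 2 (0.13) or db/db replicate 3 (0.17), and in db/db replicate 1 alone against the db/+ mice its median was -1.34 (adjusted p = 0.201; range over the camera alternatives 1.51e-06 to 0.712). Because this signal moved with 2 of the 3 db/db mice, the median of db/db replicate 1 is given beside the other gene lists that passed camera.

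**Figure D2:**
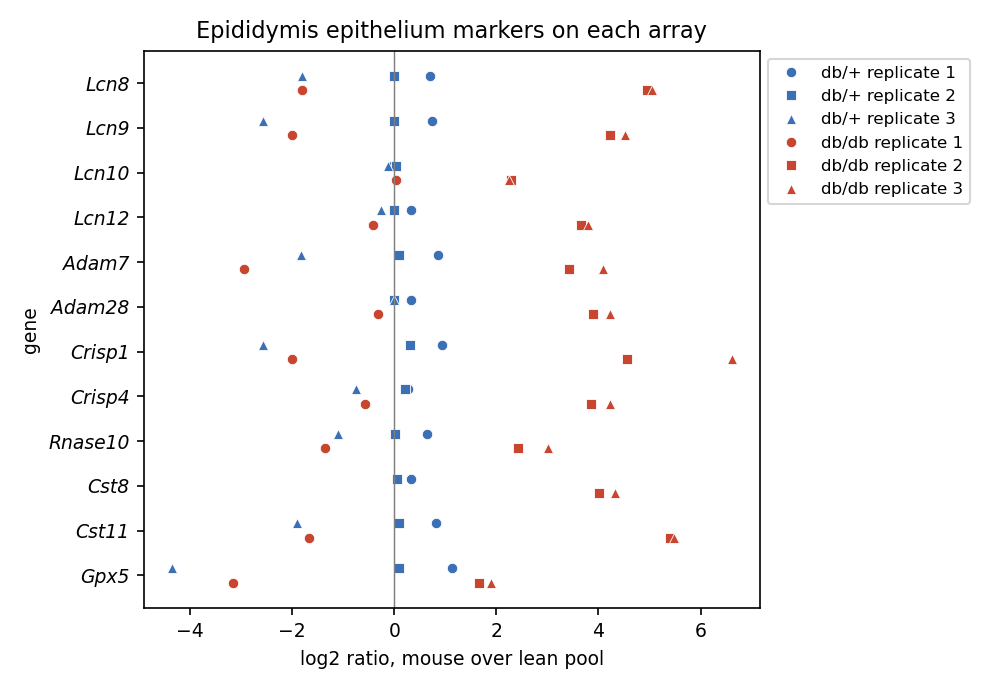
Log2 ratio of each mouse over the lean pool for 12 epididymis epithelium markers fixed before the data were examined, with db/+ mice in blue, db/db mice in red and a marker shape per replicate. db/db replicates 2 and 3 lie above the other 4 arrays for every marker, and Cst8 has no value for db/+ replicate 3 and db/db replicate 1.

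Macrophage markers were higher in db/db. Of 28 measured members 10 rose, none fell and 18 did not pass the test, with a median log2 fold change of 0.94 (camera adjusted p = 1.8e-10; adjusted p = 0.62 with an estimated correlation). Adjusted over the list alone, 20 rose and 1 fell. Mmp12, the macrophage elastase, rose by 3.43 ± 0.37 (SE), Gpnmb, a glycoprotein of lipid-laden macrophages, by 3.21 ± 0.16, Itgax, which encodes CD11c, by 2.51 ± 0.35 and Cd68 by 1.99 ± 0.30. Gpnmb was within 1% of the highest Cy5 intensity on 1 db/db array. The member that fell adjusted over the list alone was Cd163, a marker of tissue-resident macrophages. Over all genes its value of -0.82 ± 0.20 did not pass (limma adjusted p = 0.0901). Other members did not share its fall on average: Mrc1 had 0.13, Folr2 -0.07, Lyve1 -0.03 and Clec10a 0.57, and none of these passed. For Mrc1, Folr2 and Lyve1 these values averaged over db/db mice that differed. Their log2 ratios were 0.63, 0.63 and 0.48 in db/db replicate 1 and between -0.47 and 0.08 in replicates 2 and 3. The list median was 1.25 in db/db replicate 1 and 0.75 and 0.73 in replicates 2 and 3, and between -0.16 and 0.20 in the db/+ mice.

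Lysosome genes were higher as well, with 11 of 33 rising, none falling and a median of 0.58 (camera adjusted p = 9.2e-11; adjusted p = 0.62 with an estimated correlation). Adjusted over the list alone, 13 rose. Ctsk, which encodes cathepsin K, rose by 2.62 ± 0.35 (SE), and the list shares Atp6v0d2, Cd68 and Ctss with the macrophage markers. The median in db/db replicate 1 was 0.81. Cell cycle genes had 3 of 27 members rising, none falling and a median of 0.75 (camera adjusted p = 2.4e-08; adjusted p = 0.62 with an estimated correlation), with 13 rising adjusted over the list alone. The mitotic checkpoint kinase Bub1 rose by 2.42 ± 0.39, Rrm2, a subunit of ribonucleotide reductase, by 2.00 ± 0.31 and the replication helicase subunit Mcm2 by 0.73 ± 0.07. The size for Bub1 is approximate, since its mean Cy5 intensity in db/+ was 0.0200. For the list, the median in db/db replicate 1 was 1.21.

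Cytokines and chemokines moved in both directions and did not pass as a list (median 0.19, camera adjusted p = 0.14; 0.0268 without db/db replicate 2, range over the camera alternatives 2.45e-03 to 0.696). Of 31 members, 3 rose and 3 were called lower. Among the latter, Ifng had no spread in either group at a mean Cy5 intensity of 0.0633 in db/+, the kind of call that rounding alone gave in simulated data. Ccl2, the monocyte chemoattractant, rose by 2.74 ± 0.30 (SE) and Il1rn by 4.37 ± 0.36, whereas Cxcl9, a chemokine induced by interferon gamma, fell by 2.05 ± 0.21. MHC class II genes were lower: H2-Eb1 fell by 1.44 ± 0.15, H2-Ab1 by 0.95 ± 0.16 and H2-Aa by 0.83 ± 0.15, 3 of the 7 measured members, with a median of -0.80 (camera adjusted p = 2.6e-04; adjusted p = 0.62 with an estimated correlation). Interferon-stimulated genes had a median of -0.49 (camera adjusted p = 8.7e-04; adjusted p = 0.62 with an estimated correlation), but none of the 17 members passed the gene-level test and 5 were lower adjusted over the list alone. The size for H2-Eb1 is approximate, since its Cy5 intensity was within 1% of the highest of the array on all 3 db/+ arrays. In db/db replicate 1 the medians were 0.39 for the cytokine list, -0.48 for the MHC class II list and -0.45 for the interferon list.

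Genes of branched-chain amino acid breakdown formed the list with the largest share of called members. Of 23 members 14 fell and none rose (19 fell adjusted over the list alone), with a median of -0.75 (camera adjusted p = 4.5e-11; adjusted p = 0.62 with an estimated correlation). Hibch, an enzyme of valine breakdown, fell by 1.56 ± 0.22 (SE), Pccb, a subunit of propionyl-CoA carboxylase, by 1.44 ± 0.11 and Mccc1, an enzyme of leucine breakdown, by 1.38 ± 0.18. The list medians in the 3 db/db mice were -0.72, -0.71 and -1.02. Respiratory chain and citrate cycle genes had 15 of 33 members falling, none rising (25 falling adjusted over the list alone) and a median of -0.52 (camera adjusted p = 1.7e-12; adjusted p = 0.62 with an estimated correlation). Cyc1 fell by 1.06 ± 0.16 and Sdhb and Sdha, subunits of succinate dehydrogenase, by 0.95 ± 0.10 and 0.93 ± 0.14. The sizes for Sdhb and Sdha are approximate, since both were within 1% of the highest Cy5 intensity on 2 db/+ arrays. The median in db/db replicate 1 was -0.47.

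Adipocyte identity genes and adipokines were lower as a list, with 9 of 27 members falling and 1, Lep, rising (median -0.76, camera adjusted p = 8.3e-04; adjusted p = 0.62 with an estimated correlation). Adjusted over the list alone, 13 fell and 1 rose. Cfd and Retn fell as given above, and Rbp4, the retinol-binding protein, fell by 2.81 ± 0.37 (SE). The list medians were -0.31, -0.82 and -1.25 in db/db replicates 1, 2 and 3. Fatty acid synthesis genes had 6 of 18 members falling and none rising (median -0.87, camera adjusted p = 9.5e-04; adjusted p = 0.62 with an estimated correlation). Fatty acid synthase (Fasn) fell by 2.58 ± 0.22, the transketolase Tkt by 1.84 ± 0.18 and Acss2, an acetyl-CoA synthetase, by 1.69 ± 0.27. Tkt was within 1% of the highest Cy5 intensity on 1 db/+ array. The median in db/db replicate 1 was -0.76. Fatty acid oxidation genes had 4 members falling and 1, Cpt1b, rising among 21 (median -0.54, camera adjusted p = 7.1e-04; adjusted p = 0.62 with an estimated correlation), among them Ppara (-1.29 ± 0.18) and Ehhadh (-0.91 ± 0.11), with a median of -0.24 in db/db replicate 1.

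Triglyceride synthesis genes had a median of -0.38 (camera adjusted p = 0.043; adjusted p = 0.62 with an estimated correlation), with 2 of 14 members falling and 1 rising. Gpam, which starts glycerolipid synthesis, fell by 1.43 ± 0.06 (SE) and Acsl4 rose by 0.97 ± 0.17. Genes of lipolysis and its adrenergic control had a median of -0.31 with 1 of 17 members falling (camera adjusted p = 0.043; adjusted p = 0.63 with an estimated correlation). In db/db replicates 1, 2 and 3 the medians were -0.23, -0.47 and -0.71 for triglyceride synthesis and 0.00, -0.34 and -0.66 for lipolysis. Neither list passed without db/+ replicate 1 (adjusted p = 0.1 and 0.0928), db/db replicate 2 (0.0863 and 0.0996) or db/db replicate 3 (0.0546 and 0.0852). The lipolysis list also did not pass without db/+ replicate 2 (0.0972), and neither list passed with the epididymis marker median as a covariate (0.0546 and 0.13). In db/db replicate 1 alone against the db/+ mice the adjusted p were 0.173 and 0.666. Over the camera alternatives they ranged from 6.93e-03 to 0.293 and from 8.65e-04 to 0.666. Endothelial markers had a median of -0.67 with 1 of 13 members, Egfl7, falling (camera adjusted p = 7.1e-04; adjusted p = 0.62 with an estimated correlation), with medians of -0.32, -0.64 and -1.13 in db/db replicates 1, 2 and 3, and the list did not pass in db/db replicate 1 alone (adjusted p = 0.0574; range over the camera alternatives 7.71e-05 to 0.0574).

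Extracellular matrix genes had 4 of 35 members rising and none falling (median 0.22, camera adjusted p = 9.5e-04; adjusted p = 0.63 with an estimated correlation). Besides Mmp12, these included Timp1, a metalloproteinase inhibitor (2.21 ± 0.17, SE), and Lox, a collagen cross-linking enzyme (1.19 ± 0.07). The size for Timp1 is approximate, since its mean Cy5 intensity in db/+ was 0.0833. The list median was 0.75 in db/db replicate 1 against 0.00 and 0.10 in replicates 2 and 3, and the list did not pass without replicate 1 (median 0.02, adjusted p = 0.368; range over the camera alternatives 3.96e-07 to 0.368). Cholesterol synthesis genes had a median of 0.31 with 1 of 22 members rising (camera adjusted p = 0.0035, and 0.62 with an estimated correlation). The list did not pass without db/db replicate 1 (camera adjusted p = 0.115, range over the camera alternatives 3.60e-05 to 0.115). Its medians were 0.35, 0.14 and 0.23 in db/db replicates 1, 2 and 3 and 0.25, -0.17 and -0.10 in the db/+ mice, so the groups overlapped. Unfolded protein response genes had a median of 0.33 (camera adjusted p = 0.022; adjusted p = 0.62 with an estimated correlation), with Atf3 rising and the asparagine synthetase gene Asns falling among 20 members, and did not pass without db/db replicate 2 (adjusted p = 0.0865), without db/db replicate 3 (0.0535), with the epididymis marker median as a covariate (0.07) or in db/db replicate 1 alone (0.374; range over the camera alternatives 5.12e-05 to 0.374). Its medians were 0.16, 0.51 and 0.43 in db/db replicates 1, 2 and 3.

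**Figure D3:**
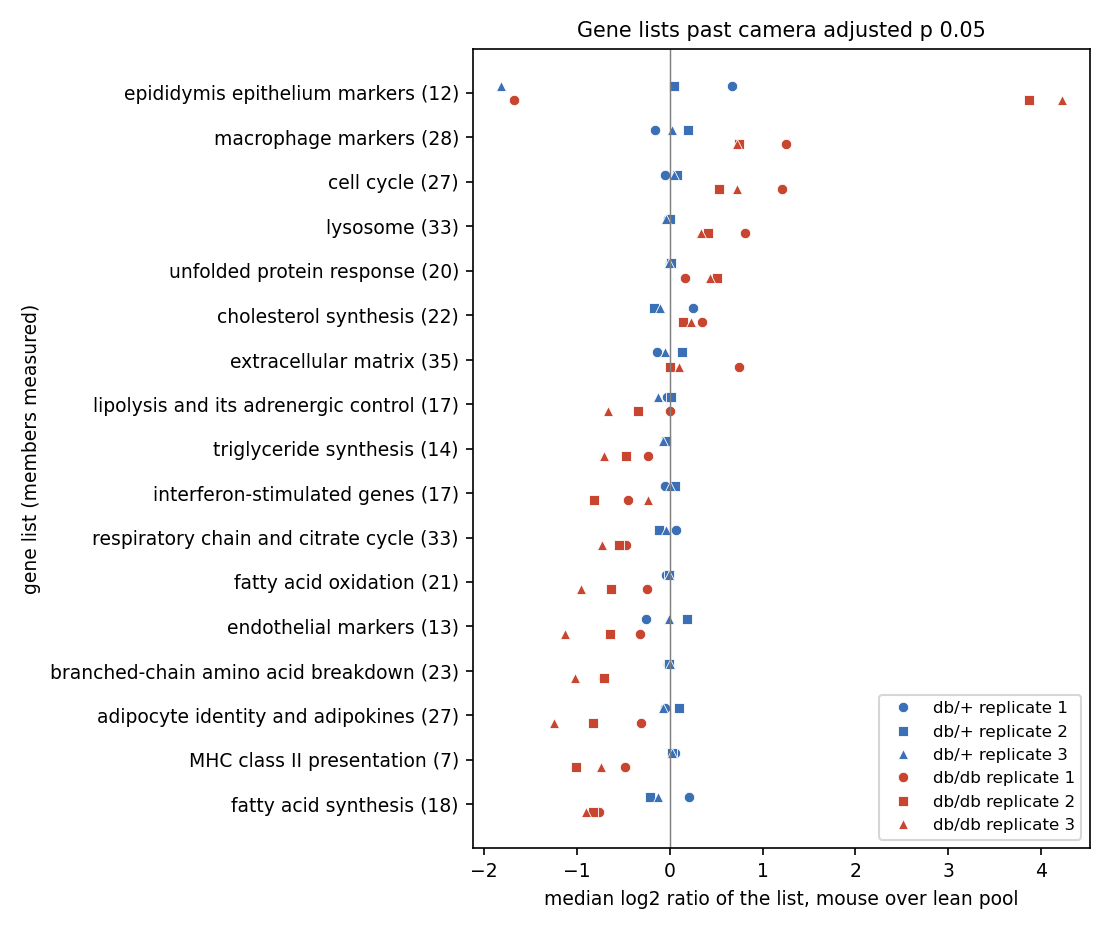
Median log2 ratio of each mouse over the lean pool for the 17 gene lists past a camera adjusted p of 0.05, with db/+ mice in blue, db/db mice in red, a marker shape per replicate and the number of measured members in parentheses. The branched-chain list lies between -1.02 and -0.71 in the db/db mice, and the epididymis list spans -1.68 to 4.22 among them.

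Several lists did not pass as a whole by camera while single members changed, and all of these but the hypoxia list passed under at least 1 alternative. Among 26 insulin signalling genes 2 rose and 3 fell (median -0.30, adjusted p = 0.058; 0.0332 without db/+ replicate 3, 0.0335 without db/db replicate 3, range over the camera alternatives 4.44e-03 to 0.147), Slc2a4, Socs1 (-0.75 ± 0.05, SE) and Hk2 (-0.70 ± 0.08) being lower. Of 15 leptin and JAK-STAT genes 2 rose and 2 fell (median -0.12, adjusted p = 0.46; range over the camera alternatives 2.54e-02 to 0.846), Stat5a with -0.86 ± 0.11. Of 14 thermogenic adipocyte genes 2 rose and 4 fell (median -0.17, adjusted p = 0.45; range 4.28e-02 to 0.67), with Cidea at -2.17 ± 0.23 and Cox8b at -1.83 ± 0.22. The 2 that rose were Ucp1 (1.19 ± 0.21) and Cpt1b (0.55 ± 0.05). Ucp1 was dim, with a mean Cy5 intensity of 0.130 in db/+ and 0.273 in db/db. Of 17 hypoxia response genes 1 rose and 4 fell (median -0.11, adjusted p = 0.46; range 0.286 to 0.67), among them Vegfa (-1.26 ± 0.21), Bnip3 (-1.17 ± 0.22) and Ndrg1 (-1.08 ± 0.17). The size for Vegfa is approximate, at a mean Cy5 intensity of 0.0933 in db/db. Of 25 antioxidant and oxidant genes 2 rose and 3 fell (median 0.33, adjusted p = 0.078; 0.0393 without db/+ replicate 1, range over the camera alternatives 2.89e-02 to 0.307): Gstm1 rose by 1.19 ± 0.16, and Gsta4 fell by 1.84 ± 0.11. Of 15 circadian clock genes 1 rose and 2 fell (median -0.42, adjusted p = 0.27; range 1.28e-02 to 0.948), with Dbp at -1.72 ± 0.28 and Per3 at -0.91 ± 0.17, while Cry1 was called higher at 0.46 ± 0.07. The size for Cry1 is approximate, since its mean Cy5 intensity was 0.0733 in db/+ and 0.110 in db/db. Of 16 immediate early genes 3 rose (median 0.21, adjusted p = 0.19; range 3.01e-02 to 0.497), namely Egr2, Atf3 (2.08 ± 0.35) and Junb (0.56 ± 0.10).

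Markers of the other cell types did not pass as lists. The median log2 fold changes and camera adjusted p were 0.00 and 0.94 for T lymphocytes, 0.00 and 0.99 for B lymphocytes, -0.13 and 0.68 for neutrophils, and -0.33 and 0.70 for mast cells. They were -0.20 and 0.27 for mesothelium, 0.09 and 0.96 for fibroblasts and progenitors, 0.00 and 0.96 for skeletal muscle, -0.14 and 0.96 for exocrine pancreas and -0.41 and 0.46 for erythrocytes. The mesothelial list went both ways with the epididymis signal of the db/db mice. Among these mice its keratins, such as Krt18 (-2.54, 2.45 and 3.10 in replicates 1, 2 and 3), followed that signal, whereas Msln (-0.54, -0.91 and -1.19) did not. Across db/+ replicates 1, 2 and 3 Krt18 did not follow it, with 0.78, -1.34 and 0.10 against epididymis medians of 0.67, 0.05 and -1.81. The mesothelial list medians were -1.10, -0.25 and -0.57 in db/db replicates 1, 2 and 3 and -0.41, 0.05 and -0.12 in the db/+ mice. In db/db replicate 1 alone against the db/+ mice, the median log2 fold change of this list was -0.86. For fibroblasts and exocrine pancreas the sign of the median differed from that of the test. In all, 17 of 34 lists passed camera with its preset correlation, 7 higher and 10 lower, and 0 passed with an estimated correlation. By fry, which asks whether the genes of a list move one way on balance, 10 passed, of which 7 also passed camera, namely the macrophage, lysosome, MHC class II, branched-chain, respiratory chain, fatty acid synthesis and triglyceride synthesis lists. The others were the insulin signalling (adjusted p = 0.046), leptin and JAK-STAT (0.034) and immediate early gene lists (0.014), which did not pass camera.

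The 3 db/+ arrays were also tested against their lean reference, with a spread shared with the db/db arrays. The mice in that pool are not given in the sources used here. Were these 3 mice among them, their mean ratio would lie near 0 by construction, so the counts give no background rate of false calls. limma called 0 genes at an adjusted p under 0.05, and 228 had an unadjusted p under 0.05. The count was 3, 11 and 1 without db/+ replicates 1, 2 and 3 and 1 without db/db replicate 3. The log2 ratios of db/+ replicates 1 and 2 had a correlation of -0.38 across probes; the labels state Cy5 for the mouse on every array, and mice compared with a pool of lean mice can deviate from it in opposite directions, so the direction was kept. Within db/db, replicates 2 and 3 had a correlation of 0.85, and replicate 1 had 0.32 and 0.29 with them. Genes are not independent replicates in these correlations.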

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

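A signal appeared in probes that the gene-level comparison did not use. Of 2214 probes with no gene name, 44 passed an adjusted p under 0.05 between db/db and db/+ by limma, 16 higher and 28 lower in db/db, adjusted over all named and unnamed probes tested separately. In the db/+ arrays against the lean reference, limma called 0 of them, with 40 at an unadjusted p under 0.05. Since the pool may hold these same mice, that count is no background rate either. Of 21236 named probes tested separately, 1309 passed between db/db and db/+, adjusted over named probes only. The share that passed was thus smaller among unnamed than among named probes. No explanation was tested.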

How the results depend on the processing

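Tests of db/db replicate 1 alone, the epididymis covariate, rounding noise, genes without spread and a minimum intensity were chosen only after the data were seen. In every alternative at least 99.3% of the 1150 calls that could be tested kept their sign. This says little about stability, since 1141 of the calls had groups that did not overlap. For these, leaving out an array could not reverse the sign. The count of calls moved widely. It was 0 by limma after quantile normalization of ratios (2176 at an unadjusted p under 0.05), 570 from Cy5 alone, 6672 with array weights, 99 for db/db arrays against the pool alone, 74 at adjusted p 0.01, 707 at 1.5-fold or more, 1792 for db/db replicate 1 alone (the lone mouse is assumed to vary like the others), and between 54 and 3417 with 1 array left out. Genes at 2-fold or more numbered 0 after quantile normalization, 1041 with array weights, 32 against the pool alone and between 18 and 943 with 1 array left out. The share of higher genes was 49.3% after loess, 48.5% against the pool alone, 63.3% for db/db replicate 1 alone, 60.3% with the epididymis covariate and between 38.3% and 58.6% with 1 array left out; quantile normalization and the block left no calls and so gave no share. Pathway lists past camera numbered 14, and 0 with an estimated correlation and 9 by fry; cell type lists numbered 3, and 0 and 1 in turn. The epididymis list reversed to -1.34 in db/db replicate 1 alone, which by construction leaves out the mice rich in its markers. The db/+ arrays against the reference gave between 0 and 11 genes with 1 array left out and 1 beside db/db replicate 1 alone. For these moves the cause was not tested. As given above, quantile normalization equalizes the spread of the arrays, and the array weights lean on 1 db/db mouse. Fewer arrays cannot account for the higher counts without db/db replicate 1. Setting array medians to 0 moved nothing, since they already were. With the replicate number as a replicate block, 0 genes passed by limma, also at 2-fold or more, with 3086 at an unadjusted p under 0.05. Same-numbered mice deviated with correlations of -0.58, -0.51 and 0.01, and 0 of the 3 db/+ mice correlated best with the db/db mouse of their own number. These values gave no sign of a pairing by number. They cannot exclude one, since deviations from a mean of 3 arrays constrain one another. For single named genes, over all alternatives 971 values stayed on their side of the threshold, 11 newly passed and 463 no longer passed. Low signal limits dim genes: without the dimmest 25%, 1492 genes passed, with rounding noise 811 and without genes lacking spread 1041.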

Other observations

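Tests of the epididymis marker medians, the macrophage markers in db/db replicate 1, hybridisation quality, dilution by epididymal tissue, a lower share of adipocytes and other splits were chosen only after the result was seen; the others were written beforehand. The cell cycle median was 1.21 in db/db replicate 1 and 0.53 and 0.72 in replicates 2 and 3, and the difference between the mice was not tested.

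In the authors' deposited table, probes with a p-value under 0.01 against the pool numbered 3176, 3605 and 4970 for the 3 db/db mice and 488, 431 and 104 for db/+ replicates 1, 2 and 3. Of these, 402 were higher and 86 lower in db/+ replicate 1, and 26 were higher and 405 lower in db/+ replicate 2.

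db/db replicate 1 stood apart from replicates 2 and 3, with correlations of ratios across probes of 0.32 and 0.29 against 0.85 between those 2. Its correlation with db/+ replicate 2 was 0.33, as high as with its own group; all ratios share the reference pool. A poor hybridisation of the array is argued against by the reference channel, whose lowest mean correlation with the other arrays was 0.990 among the db/db arrays and 0.988 among all 6. That channel holds the lean pool on every array, so it cannot show a fault in the RNA, amplification or labelling of the mouse itself. A mislabelled db/+ mouse is argued against by its macrophage markers, which exceeded the highest db/+ mouse by 1.05 where the db/+ mice spanned 0.36; the test written beforehand, the sign of 3411 genes called from the other 5 arrays, fell between its bounds with a median of 0.27 and 73.8% of genes in the direction of the call. A candidate explanation is epididymal tissue carried along in replicates 2 and 3. Their preset marker medians exceeded those of the other 4 arrays by at least 3.20 on the log2 scale. Leaving out 414 genes that differed 2-fold between db/+ arrays raised the correlation from 0.33 to 0.54, short of the 0.6 set beforehand. That filter cannot decide the question, since it keeps markers that varied little among the db/+ mice. Lcn10, for example, had -0.05, 0.03 and -0.13 in the db/+ mice and 2.29 and 2.25 in db/db replicates 2 and 3. A difference between the db/db mice themselves stays open and was not tested.

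Branched-chain, respiratory chain and adipocyte genes were lower in db/db. Dilution by epididymal tissue as the whole cause is argued against by the fit with the epididymis score as a covariate, in which 3 of the 3 lists stayed lower (medians -0.59, -0.46 and -0.54; camera adjusted p = 5.1e-11, 2.7e-11 and 0.0039). A lower share of adipocytes alone would raise the markers of all other cell types alike, but the macrophage and endothelial medians moved apart by 1.60. Both medians were known when this test was chosen, and the endothelial list did not pass by fry (adjusted p = 0.077). The test bears only on a lower share as the sole change and cannot exclude one together with changes in other cells. By camera with an estimated correlation, the branched-chain, respiratory chain and adipocyte list calls were all lost (adjusted p = 0.62). The genotype, a larger number of macrophages and a lower share of adipocytes beside other changes may contribute and stay open.

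A pair of hypotheses on macrophage state, each tested on genes whose values had not been looked at, were not borne out. After Ocstamp, Ctsk and Atp6v0d2 were seen among the rises, other genes of multinucleated macrophages and osteoclasts might have risen too. The median over 7 measured genes was 0.14, and 1 of them, Dcstamp, passed the gene-level threshold (1.88 ± 0.27, SE). camera gave p = 0.066, and p = 0.38 with an estimated correlation. After low values were seen for Retnla, which fell by 2.24, and for Cd209f (-2.16, adjusted p = 0.0779) and Cd209b (-1.47, adjusted p = 0.124), which did not pass, other genes of resident macrophages might have fallen. The median over 7 measured genes was -0.37, and 1 of them, Gas6, passed the threshold (-0.77 ± 0.12). camera gave p = 0.089, and p = 0.47 with an estimated correlation.

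The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1149 genes with the series matrix values, the highest other split gave 4, and 1 of the 10 splits, the real one, reached that count.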
